A study of Mus musculus with 8 samples.

How the data were processed

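Gene expression was measured in whole skin of old female flaky tail mice, a strain that carries the matted mutation of Tmem79 and the flaky tail mutation of Flg. There were 2 groups, lesional skin of the neck and non-lesional skin of the flank, with 4 arrays each, numbered 1 to 4 in the titles. Body site and lesion status changed together, so no comparison here separates them.

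Per the labels, RNA was isolated with TRIzol, purified on a column, amplified and labelled with Cy3. Per the file headers, the files come from Feature Extraction 10.7.1.1, whereas the submitters' processing notes name Agilent Feature Extraction 9.5.1.1. The deposited signal of each spot is a linear intensity, background-corrected per the file headers, and not scaled between arrays. Each array held 59305 spots that were not controls, for 56605 probes. The authors' deposited value table also holds linear intensities. Its columns share a median of 41.3, and on every array the median absolute log2 difference from a quantile normalization of the processed signals was 0 (largest 0.326). Its scale was therefore settled from the data, no centring to 0 was applied and higher values mean more signal, while the tool that made it is not given in the labels.

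The log2 processed signal was taken, spots of a probe were averaged, the 75th percentile of each array was subtracted, and 93 probe values with an outlier flag were left out. Probes well above background on all 4 arrays of at least 1 site were kept, 29289 in all, and the probe with the highest mean stood for its gene. Of the probes, 32994 were named through their accession in the RefSeq table of GRCm38.p6 and the others by the file's own name, which left 19768 gene names to test. Some names are older ones, such as Il1f5, Il1f6 and Il1f8 for Il36rn, Il36a and Il36b. Genomic positions were not used here.

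The sites were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, site only), at a Benjamini-Hochberg adjusted p under 0.05. Differences are log2 values, neck minus flank, ± SE with 4 arrays per site. A called gene that was not well above background on any array of 1 site is given a bound against the detection floor (per array, the lowest signal of any probe well above background, or the signal of the gene itself where that is higher), written "at least N-fold". The 41 gene lists, the comparison, the rule for named genes and the alternatives were fixed before the data were examined. The 39 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and their array means by a two-sided exact permutation test over 70 arrangements, whose smallest p is 0.0286. The rule named the 12 largest differences in each direction among called genes with a gene symbol, the same sign in all 4 same-numbered pairs and signal above background in both sites, the 3 largest bounds in each direction, up to 4 called members of each list with the largest differences (or the 2 members with the lowest p where none was called), and Tmem79, Flg, Il4, Il13, Il17a, Ifng, Tslp, Il33 and Il31. Any other named gene was chosen after its values were seen.

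Same-numbered arrays of both sites deviated together from their site's mean, with correlations across genes of 0.448, 0.238, 0.268 and 0.429 for numbers 1 to 4, each above 0.1, so the numbers were taken to pair the samples, although neck replicate 3 correlated best with flank replicate 2 (0.544). The labels do not say that a number is 1 animal, or that the arrays of a site came from separate animals. If they did not, p-values measure only the spread between these samples. Slide 1 held both arrays of number 1, slide 2 those of numbers 2 and 3, and slide 3 those of number 4, so every slide held both sites. Same-numbered arrays thus always shared a slide, as did neck replicate 3 and flank replicate 2. The correlations cannot tell a pairing by number from an effect of the slide.

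The alternatives were the number as a fixed or random replicate block, the slide as a block, normexp background correction with an offset of 50, quantile normalization, scaling to the 75th percentile or median of probes detected on all arrays, the authors' deposited values, no filter or a filter on all arrays, the mean of a gene's probes, a trended and robust prior, array weights, camera on ranks, and leaving out each array or each number. A further 3 were chosen after seeing the data: leaving out flank replicate 1 with either replicate block, and leaving out flank replicates 1 and 3. The median signal of an array lay between 27.0 and 68.7, so the normexp offset of 50 by itself pulls differences of dim genes towards 0. A smaller normexp value of a dim gene does not by itself show that its difference is absent. The fit was tested on simulated data with 19742 genes. It called 4 of 67 genes changed 2-fold, 53 of 67 changed 4-fold and 64 of 66 changed 16-fold, and 7 of 19512 unchanged genes. The simulated noise was independent between genes and arrays, with no slide effect, pairing or outlying array. These rates therefore check the fit and are not the error rates of the real comparison.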

Results

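Lesional neck skin was compared with non-lesional flank skin of old flaky tail mice, with 4 arrays of each. Between 53.8% and 64.0% of spots were well above background on each array, and 0 were saturated. The 75th percentile of the signal lay between 289 (neck replicate 2) and 813 (neck replicate 1). Over all genes, the flank arrays correlated with each other at 0.903 to 0.947 and the neck arrays at 0.939 to 0.963. Flank arrays correlated with neck arrays at 0.865 to 0.947, a range that overlaps both. The first principal component held 37.3% of the variance and parted the neck arrays from the flank arrays. The number of arrays limits the precision of every value below.

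Neck skin expressed far more of a set of epidermal protease, protease inhibitor and cornification genes than flank skin, and far less of the trunk Hox genes. Among called genes above background in both sites, Wfdc12, a protease inhibitor of the whey acidic protein type, had the largest increase, 7.51 ± 0.52 (adjusted p = 0.000486, higher in 4 of 4 pairs). It was followed by Fabp7, a fatty acid binding protein (6.71 ± 0.86), Tmprss11a, a membrane serine protease (6.60 ± 0.68), Rptn, which encodes the cornified envelope protein repetin (6.36 ± 0.94), and Serpinb3a, a protease inhibitor (6.33 ± 1.07). At the other end were Hoxb7 (-7.64 ± 0.76), the suprabasal keratin Krt77, 128-fold lower in neck skin, and Jchain, the joining chain of secreted antibodies (-6.62 ± 1.21). Hoxb7 and Jchain were above background on 1 of 4 neck arrays and Krt77 on 3, so the size of these differences is uncertain, and under normexp background correction they were at -4.52, -3.75 and -5.57. Wfdc12 was above background on 3 of 4 flank arrays and at 6.12 under normexp. Of 19768 genes, 373 were higher and 291 lower in neck skin by limma. At least 2-fold were 369 and 289 of them, and 661 of the 664 had the same sign in all 4 pairs. Where the arrays of both sites are fully separated, any pairing gives this, and the rule required it of the genes named by size. It is therefore not separate support for the calls.

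**Figure D1:**
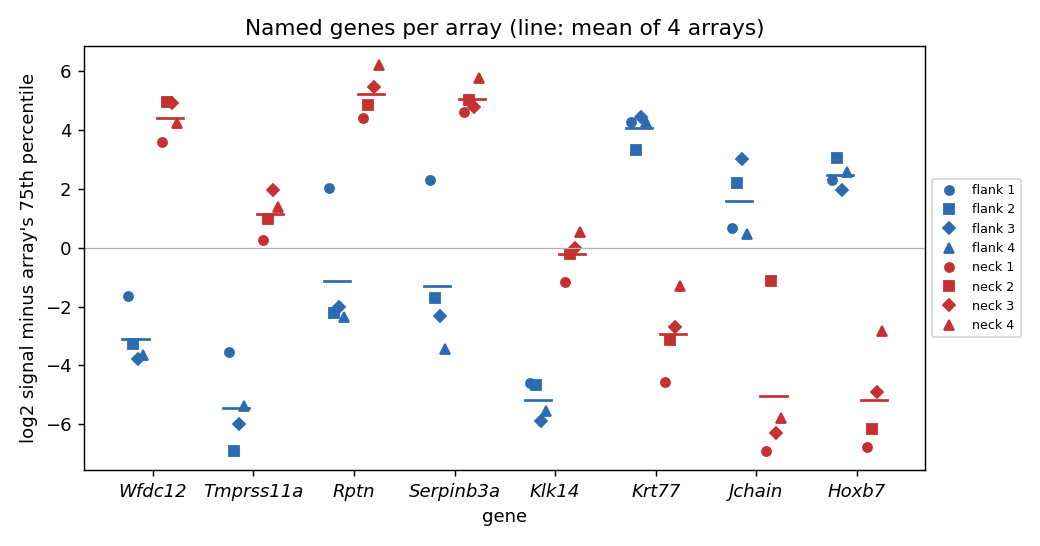
Log2 signal minus the array's 75th percentile (y axis) of 8 named genes (x axis), with 1 point per array and a line at the mean of the 4 arrays of each site. Wfdc12 has a mean of -3.09 in flank and 4.42 in neck skin.

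Other large increases were those of Fetub (5.64 ± 0.35), the myosin light chain gene Myl7 (5.61 ± 0.39), Olah, a thioesterase of fatty acid synthesis (5.61 ± 0.45), Cstdc6 (5.27 ± 1.12), the urate oxidase gene Uox (5.16 ± 0.97), the ribonuclease Rnase2b (5.07 ± 0.70) and the kallikrein Klk14 (4.95 ± 0.43). Spocd1, Nmu, which encodes the neuropeptide neuromedin U, and the protease inhibitor Spink6 were at least 28.4-fold, 22.5-fold and 11.3-fold higher in neck skin. The decreases included Hoxa7 (-5.56 ± 0.26), the transcript Mira (-5.11 ± 0.33), the B cell chemokine Cxcl13 (-5.06 ± 1.09), the hormone subunit Gpha2 (-4.91 ± 0.61), Hoxc9 (-4.75 ± 0.54), Dab1 (-4.60 ± 0.33), the alcohol dehydrogenase Adh6a (-4.25 ± 0.33), Wfdc3 (-4.21 ± 0.69) and Il31ra, a subunit of the interleukin-31 receptor (-3.97 ± 0.32). Hoxb8, Hoxb6 and Hoxa5 were at least 26.3-fold, 25.2-fold and 12.03-fold lower. In the lower site Klk14 and Dab1 were above background on 1 of 4 arrays, Tmprss11a, Myl7, Gpha2, Hoxc9 and Il31ra on 2, and Serpinb3a, Rnase2b, Cxcl13 and Wfdc3 on 3, which limits the size of their differences. Under normexp Tmprss11a, Myl7, Klk14, Cxcl13, Gpha2, Hoxc9, Dab1, Wfdc3 and Il31ra were at 3.69, 3.55, 2.44, -3.25, -3.05, -2.50, -1.37, -2.94 and -1.67. Cxcl13 passed in only 1 of the 8 fits with 1 array left out. The genes given as bounds, whose floor is set by the main processing, were smaller than these under normexp: Spocd1, Nmu and Spink6 at 3.24, 2.79 and 2.04, and Hoxb8, Hoxb6 and Hoxa5 at -3.33, -2.92 and -2.16. With the fixed replicate block Cstdc6 and Wfdc3 missed the threshold (adjusted p = 0.0586 and 0.0571), and under quantile normalization Cstdc6 and Cxcl13 (0.0525 and 0.0557).

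Of the mutated genes, Tmem79 did not pass (0.74 ± 0.30, adjusted p = 0.247). No probe carries the symbol Flg, but a pair of transcripts that the files describe as filaggrin was higher in neck skin, by 2.87 ± 0.32 and 3.16 ± 0.35 (adjusted p = 0.00431 and 0.00377, 4 of 4 pairs each).

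Cornified envelope and terminal differentiation genes were higher as a group. Of 43 tested, 18 were higher, 1 was lower and 24 did not pass, with a median of 1.17 (camera adjusted p = 1.22e-13, and adjusted p = 0.434 with an estimated correlation). Rptn led, followed by the transglutaminase Tgm3 (3.15 ± 0.32) and the suprabasal keratin Krt1 (3.14 ± 0.38), and Krt77 was the lone decrease. Adjusted over the list alone, 25 were higher and 2 lower, and with the fixed replicate block 5 and 2. The median was 0.36 on slide 1, 1.38 on slide 2 and 1.31 on slide 3 (camera adjusted p = 2.92e-10 with the slide as a block).

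Activated keratinocyte genes, which wounded or inflamed epidermis switches on, had a median of 4.01, and 36 of 36 lay above 0 (camera adjusted p = 6.7e-17, and adjusted p = 0.439 with an estimated correlation). The median was 3.74 with Serpinb3d at its bound. On their own 5 passed, the inhibitors Serpinb3a, Serpinb3c (4.44 ± 0.71) and Serpinb3d (at least 7.998-fold higher, at 1.90 under normexp), the stefin Stfa3 (3.14 ± 0.67, but adjusted p = 0.0665 with the fixed replicate block and 0.0642 under quantile normalization) and, chosen after its values were seen, Serpinb3b (2.17 ± 0.49), and 31 did not pass. Serpinb3b also missed the threshold with the fixed replicate block. The Serpinb3 and Stfa probes were not checked for specificity, so the calls of the related Serpinb3 genes may not be separate ones. There were 31 past the threshold adjusted over the list alone. Of members chosen after their values were seen, the stress keratins Krt16 (4.96 ± 1.28, adjusted p = 0.0746) and Krt6b (8.34 ± 2.43, adjusted p = 0.105) did not pass. The list mean was 4.08 on flank replicate 1, -0.25 to 0.11 on the other flank arrays and 4.31 to 4.94 on the neck arrays. Without flank replicate 1, 26 members passed, with the random replicate block 24 and with the fixed replicate block 3. The median was -0.018 on slide 1, 5.05 on slide 2 and 4.11 on slide 3 (camera adjusted p = 9.09e-14 with the slide as a block).

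**Figure D2:**
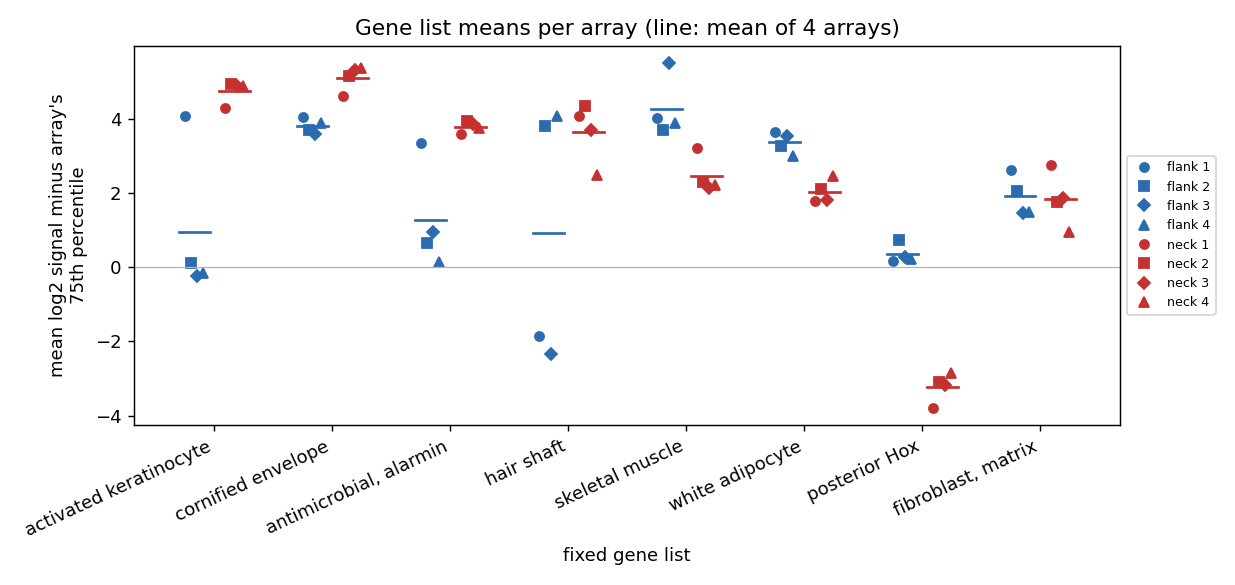
Mean log2 signal minus the array's 75th percentile (y axis) over the tested members of 8 fixed gene lists (x axis), with 1 point per array and a line at the mean of the 4 arrays of each site. Flank replicate 1 lies at 4.08 for activated keratinocyte genes, near the neck arrays, and at 0.18 for posterior Hox genes, near the other flank arrays.

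Of 17 antimicrobial peptide and alarmin genes, Wfdc12, the chitinase-like Chil1 (3.12 ± 0.59) and Wfdc5 (1.47 ± 0.32) were higher and 14 did not pass. The list median was 2.32 (camera adjusted p = 3.69e-07, and adjusted p = 0.487 with an estimated correlation). Adjusted over the list alone, 12 passed, and 10 passed without flank replicate 1, 9 with the random replicate block. In the interleukin-17, interleukin-22 and interleukin-36 list, 3 of 14 were higher, all of the interleukin-36 family: Il1f6 (3.64 ± 0.81), Il1f8 (2.65 ± 0.51) and Il1f5, the receptor antagonist (2.35 ± 0.41). Its median was 0.99 (camera adjusted p = 0.0109, adjusted p = 0.701 with an estimated correlation, and exact permutation p = 0.0857). Adjusted over the list alone 6 passed, and 5 without flank replicate 1. The list's call ended without flank replicate 2 or without number 4 (adjusted p = 0.0562 and 0.0546). With the fixed replicate block Chil1, Wfdc5, Il1f6, Il1f8 and Il1f5 missed the threshold (adjusted p = 0.0582, 0.0589, 0.0700, 0.0647 and 0.0586), as did Wfdc5 with the slide as a block (0.0502) and Wfdc5 and Il1f6 under quantile normalization (0.0503 and 0.0615). The antimicrobial median was -0.13, 2.49 and 3.35 on slides 1, 2 and 3 and the interleukin median -0.16, 1.13 and 1.65 (camera adjusted p = 8.08e-06 and 0.0324 with the slide as a block).

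Il4, Il13 and Il31 were well above background on 0 of 8 arrays and Ifng on 1 neck array. Il17a (2.78 ± 0.87, adjusted p = 0.129), Tslp (-0.51 ± 0.45, or -0.23 under normexp) and Il33 (0.53 ± 0.58) did not pass. Il17a passed without flank replicate 1 (3.75, adjusted p = 0.00249), with the random replicate block (0.0409) and with array weights (0.0418), and was 0.88 under normexp (adjusted p = 0.148). Of 18 type 2 genes, Arg1 was higher (0.99 ± 0.22), and Il31ra and Retnla (-2.05 ± 0.39) were lower. Scaled to probes detected on all arrays, Arg1 missed the threshold (adjusted p = 0.0765). The list did not pass (median -0.078, adjusted p = 0.449). By limma 0 of 20 genes of interleukin-1, interleukin-6 and tumor necrosis factor inflammation passed, with Il1rn at 1.44 ± 0.38 and Tnfrsf1b at 1.18 ± 0.38, and 5 were higher at an unadjusted p under 0.05. Of 10 neutrophil and monocyte chemokine genes 0 passed, with Cxcr2 at 2.75 ± 0.96 and Cxcl5 at 3.16 ± 1.17, and 2 were higher at an unadjusted p under 0.05. Under normexp Cxcr2 was at 1.64 and Cxcl5, above background on 1 of 4 flank arrays, at 1.19. Both lists missed the threshold (medians 0.28 and 0.47, adjusted p = 0.449 and 0.413). They passed without flank replicate 1 (medians 0.65 and 1.20, adjusted p = 0.0229 and 0.00579) and without flank replicates 1 and 3 (0.00982 and 0.00679), and the chemokine list without number 1 (0.0256). Interferon response genes were lower, with a median of -0.38 (camera adjusted p = 0.00677, adjusted p = 0.701 with an estimated correlation, and exact permutation p = 0.286). Of 23, 1 passed, Usp18, which removes the ubiquitin-like protein Isg15 (-2.77 ± 0.34, or -1.59 under normexp). The list's call ended without flank replicate 1, neck replicate 4, number 1 or flank replicates 1 and 3 (adjusted p = 0.126, 0.0558, 0.254 and 0.118) and with only the probes above background on all arrays (0.0578). Its median was -0.16 without flank replicate 1 and -0.17 without number 1, and ran from -0.83 to -0.16 over all fits with an array or number left out. Its median was -1.68, -0.26 and -0.11 on slides 1, 2 and 3 (camera adjusted p = 0.00489 with the slide as a block).

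Barrier lipid gene lists were higher in neck skin by camera at its preset correlation, but not with an estimated correlation, and few members passed. Of 25 ceramide and acylceramide synthesis genes, the desaturase Degs1 (1.65 ± 0.35), the sphingomyelinase Smpd1 (1.33 ± 0.26) and the lipoxygenase Aloxe3 (1.08 ± 0.23) were higher. The median was 1.03 (camera adjusted p = 5.44e-09, and adjusted p = 0.459 with an estimated correlation). Of 22 cholesterol synthesis genes, Hsd17b7 was higher (1.46 ± 0.31). The median was 0.77 (camera adjusted p = 2.25e-06, and adjusted p = 0.547 with an estimated correlation). In these lists 15 and 8 were higher adjusted over the list alone, and 9 and 4 over all genes without flank replicate 1. The plakophilin Pkp1 of the 18 cell junction genes was higher (1.07 ± 0.20) and Krt15 of the 15 basal keratinocyte genes lower (-1.66 ± 0.34). Neither list passed (adjusted p = 0.228 and 0.693). With the fixed replicate block Degs1, Smpd1, Hsd17b7 and Pkp1 missed the threshold (adjusted p = 0.0759, 0.0653, 0.0627 and 0.0515). Under quantile normalization Degs1, Smpd1, Aloxe3 and Pkp1 did so (0.0579, 0.0578, 0.0798 and 0.0859), and Aloxe3 also under normexp (0.0508). The ceramide median was 0.055, 1.20 and 1.45 on slides 1, 2 and 3 and the cholesterol median -0.11, 0.95 and 1.46 (camera adjusted p = 3.31e-07 and 2.12e-05 with the slide as a block).

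Hair shaft and inner root sheath genes had a median of 3.13, with 47 of 48 above 0 (camera adjusted p = 3.23e-06, and adjusted p = 0.743 with an estimated correlation). Their array means gave an exact permutation p of 0.286. Krt84 (3.65 ± 0.75) and Mt4 (3.17 ± 0.57) passed, Krt84 not with the fixed replicate block (adjusted p = 0.0589). The count was 2 adjusted over the list alone. The list mean was -1.86 and -2.34 on flank replicates 1 and 3, 3.81 and 4.09 on flank replicates 2 and 4, and 2.49 to 4.35 on the neck arrays. Without flank replicates 1 and 3, an alternative chosen after seeing those values, the list was lower in neck skin (median -0.29, adjusted p = 0.00295). Without number 1, or without flank replicate 1 with the fixed replicate block, it did not pass (adjusted p = 0.0558 and 0.0738). The median was 7.004 on slide 1, 3.17 on slide 2 and -1.78 on slide 3 (camera adjusted p = 0.000195 with the slide as a block). Of 17 follicle stem cell and outer root sheath genes Barx2 was higher (1.23 ± 0.27), and of 23 sebaceous gland genes Cyp2e1 was lower (-2.93 ± 0.61). Both missed the threshold with the fixed replicate block (adjusted p = 0.0508 and 0.0589), as did Barx2 under quantile normalization (0.107). Neither list passed with all arrays (medians -0.31 and 0.11, adjusted p = 0.228 and 0.523). The follicle stem cell list passed without flank replicates 1 and 3 (median -1.09, adjusted p = 0.00449), and the sebaceous list without number 4, with the opposite sign (median -0.34, adjusted p = 0.0257).

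Hox genes were lower in neck skin. Of 13 tested genes of paralog groups 6 to 13, 9 were lower and 4 did not pass, with a median of -3.55, or -3.26 with Hoxb6 and Hoxb8 at their bounds (camera adjusted p = 6.62e-18, and adjusted p = 0.0243 with an estimated correlation, the 1 list call that held). Of 11 tested genes of groups 1 to 5, 6 were lower and 5 did not pass, with a median of -2.17, or -1.74 with Hoxa5 and Hoxb5 at their bounds (camera adjusted p = 5.44e-09, and adjusted p = 0.243 with an estimated correlation). Under normexp the posterior median was -1.25 and the anterior -1.20. Hoxa3 (-3.36 ± 0.54) and Hoxb4 (-2.88 ± 0.48) were lower, and Hoxb5 was at least 6.15-fold lower. Under normexp Hoxa3 was at -2.12 and Hoxb5 at -1.29. Hoxc4 (0.90 ± 0.45) and Hoxc5 (0.19 ± 0.30), chosen after their values were seen, did not pass. Adjusted over the list alone, 11 posterior and 8 anterior genes were lower. The posterior median was -4.57, -3.16 and -2.42 on slides 1, 2 and 3 and the anterior median -2.51, -1.71 and -1.99 (camera adjusted p = 4.04e-14 and 7.34e-08 with the slide as a block). Of 26 other positional transcription factors, Pitx1 was higher (4.46 ± 0.55), and the list did not pass (adjusted p = 0.449).

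**Figure D3:**
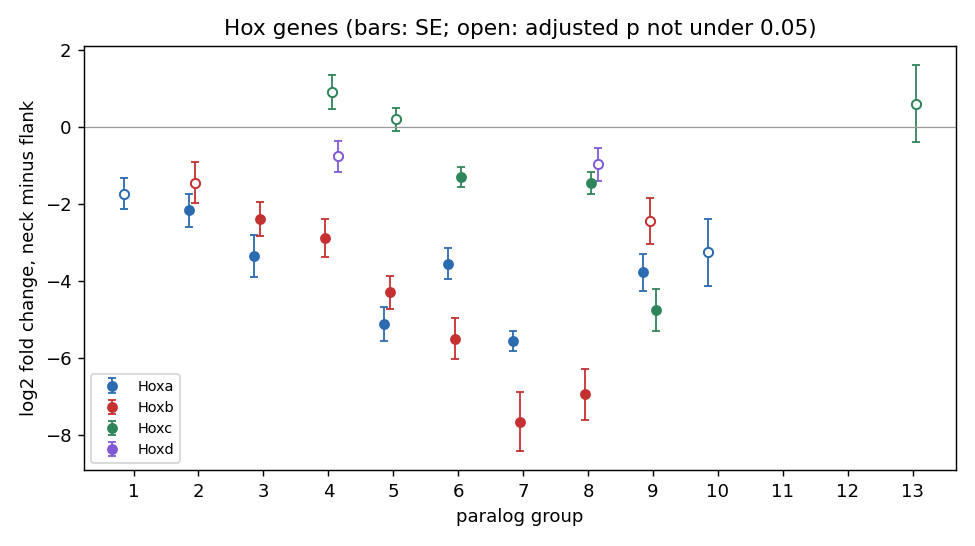
Log2 fold change of each tested Hox gene, neck minus flank (y axis), by paralog group (x axis), with SE bars, colours for the 4 clusters and open points for genes that did not pass. Hoxb7 lies lowest at -7.64, and the values of genes not above background in neck skin (Hoxa5, Hoxb5, Hoxb6 and Hoxb8) are fitted values, not bounds.

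Skeletal muscle genes were lower in neck skin, with 11 of 36 called, 35 of 36 below 0 and a median of -1.82 (camera adjusted p = 1.1e-23, and adjusted p = 0.434 with an estimated correlation). They included Actn3 (-2.86 ± 0.48), the calcium channel Ryr1 (-2.61 ± 0.50), Mybpc2 (-2.57 ± 0.53) and titin, Ttn (-2.49 ± 0.52). White fat cell genes were lower too, with 8 of 20 called and a median of -1.48 (camera adjusted p = 1.64e-12, and adjusted p = 0.243 with an estimated correlation). Among them were the carbonic anhydrase Car3 (-2.47 ± 0.32), resistin, Retn (-2.23 ± 0.30), Trarg1 (-2.18 ± 0.47) and perilipin, Plin1 (-2.18 ± 0.46). Adjusted over the list alone, 31 and 16 were lower. The counts were 26 and 15 with the random replicate block and 7 and 5 with the fixed one, and 2 fat cell genes passed without flank replicate 1. With the fixed replicate block Mybpc2, Trarg1 and Plin1 missed the threshold (adjusted p = 0.0544, 0.0609 and 0.0771), and Plin1 also with the slide as a block (0.0548). Trarg1, above background on 2 of 4 neck arrays, was at -0.61 under normexp and did not pass (adjusted p = 0.208). The muscle median was -0.97, -2.47 and -1.71 on slides 1, 2 and 3 and the fat median -1.96, -1.67 and -0.62 (camera adjusted p = 3.38e-18 and 1.71e-10 with the slide as a block).

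Schwann cell and nerve genes had a median of -0.82 with 1 of 12 called and 5 lower when adjusted over the list alone (camera adjusted p = 0.00291, and adjusted p = 0.459 with an estimated correlation). Melanocyte genes had a median of -0.63 with 0 of 10 called by limma and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.00677, adjusted p = 0.547 with an estimated correlation, and exact permutation p = 0.257). Sox10 was at -1.16 ± 0.32 (-0.54 under normexp) and Mitf at -0.65 ± 0.31, and without flank replicate 4 or number 4 the melanocyte call ended (adjusted p = 0.0594 and 0.178). The Schwann cell call ended without flank replicates 1 and 3 (0.0600). On slides 1, 2 and 3 the Schwann cell median was -0.55, -0.82 and -0.71 and the melanocyte median 1.04, -0.66 and -2.03 (camera adjusted p = 0.00294 and 0.0107 with the slide as a block). Brown fat genes, with 0 of 12 called, Zic1 at -2.39 ± 0.58 and Cpt1b at -2.01 ± 0.50, did not pass (median -1.04, adjusted p = 0.0734). The members split, with 7 below 0 and 5 above, and adjusted over the list alone 3 were lower and 1 higher. The median was -0.50 without flank replicate 3. The list passed without flank replicate 2, 3 or 4, neck replicate 1, or number 2 or 3 (adjusted p = 0.0307, 0.0302, 0.0352, 0.0343, 0.0346 and 0.0448), and on all arrays under normexp (0.0319) or with no filter on dim probes (0.00223).

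Leukocyte genes moved both ways. Of 21 T cell genes, Icos (2.95 ± 0.56), Cd5 (2.48 ± 0.32) and Cd6 (1.47 ± 0.28) were higher and Trat1 was at least 3.81-fold lower (list adjusted p = 0.969). Of 9 B and plasma cell genes, Jchain, Cd79b (-2.81 ± 0.56) and Irf4 (-1.88 ± 0.38) were lower (list adjusted p = 0.217, or 0.0178 with no filter on dim probes). Of 14 mast cell genes, Rab27b was higher (1.45 ± 0.31), and the receptor Mrgprb2 (-2.87 ± 0.36) and Hpgds (-1.76 ± 0.34) were lower (list adjusted p = 0.539). The cytotoxic granule gene Nkg7 was lower (-3.22 ± 0.50), the 1 called of 4 tested in a list too small for camera, as was the basophil and eosinophil list (3 tested, 0 called, Ear2 at -0.82 ± 0.37 and Ear6 at 0.92 ± 0.60, or -0.55 and 0.45 under normexp). With the fixed replicate block Cd6, Cd79b, Rab27b and Hpgds missed the threshold (adjusted p = 0.0605, 0.0544, 0.0582 and 0.0515), and Rab27b also under quantile normalization (0.0578). Under normexp Trat1, Cd79b, Irf4, Mrgprb2 and Hpgds did not pass and were at -0.94, -1.32, -1.13, -0.998 and -0.95 (adjusted p = 0.216, 0.140, 0.0715, 0.0526 and 0.0702), so the bound of Trat1 holds only for the main processing. Cd79b was above background on 2 of 4 neck arrays and Mrgprb2 on 1, while Icos, Cd6 and Nkg7 were at 1.91, 0.97 and -1.90 under normexp.

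The neutrophil list was higher with a median of 1.29 (camera adjusted p = 0.0385, adjusted p = 0.701 with an estimated correlation, and exact permutation p = 0.143), or 0.61 under normexp. Its called members were Asprv1 (1.52 ± 0.33), which the cornified envelope list also holds, and Mmp9, which was lower (-1.95 ± 0.40). Asprv1 missed the threshold with the fixed replicate block or the slide as a block (adjusted p = 0.0771 and 0.0537), and under quantile normalization both Asprv1 and Mmp9 did (0.0664 and 0.0638). Mmp9, above background on 2 of 4 neck arrays, was at -0.76 under normexp (adjusted p = 0.144). Adjusted over the list alone, 6 were higher and 1 lower. As fixed, the neutrophil list also shares S100a8, S100a9, Camp and Ltf with the antimicrobial list and Cxcr2 with the chemokine list. It shares Il36g with the interleukin-36 list as well, so its shift is not independent of those lists. The list's call ended without flank replicate 2 or 3, neck replicate 1, 2 or 4, or number 2, 3 or 4 (adjusted p = 0.119, 0.0822, 0.0784, 0.0578, 0.0755, 0.141, 0.0541 and 0.0935). It also ended with no filter on dim probes (median 0.40, adjusted p = 0.0631). Its median was -0.19, 1.65 and 1.64 on slides 1, 2 and 3 (camera adjusted p = 0.0325 with the slide as a block). Of 5 gamma-delta T cell genes 5830411N06Rik was higher (2.67 ± 0.43, or 1.38 under normexp), and the list did not pass (adjusted p = 0.108). It passed without flank replicate 1 or 4 (adjusted p = 0.0384 and 0.0486) and with no filter on dim probes (0.0216). Of 18 itch and sensory nerve genes Il31ra and F2rl1 (-1.30 ± 0.29) were lower (list adjusted p = 0.770). F2rl1 did not pass under normexp (-0.47, adjusted p = 0.271) or quantile normalization (0.0625). Of 21 oxidative stress genes, Cbr3 (1.90 ± 0.34) and Gpx2 (1.97 ± 0.43) were higher and Gpx3 (-2.15 ± 0.25) and Aox1 (-1.82 ± 0.38) lower. Aox1 did not pass with the fixed replicate block (adjusted p = 0.0623), nor Gpx2 under quantile normalization (0.0781). The list did not pass (adjusted p = 0.904).

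By limma 0 members passed among 27 fibroblast and dermal matrix genes (median -0.090, Thbs2 at -1.10 ± 0.47, Dpp4 at -0.65 ± 0.34), 18 blood vessel genes (-0.22, Kdr at -0.98 ± 0.42, Robo4 at -0.68 ± 0.39), 6 lymphatic genes (-0.34, Reln at -0.92 ± 0.73, or -0.36 under normexp, Lyve1 at -0.53 ± 0.64) and 25 macrophage and monocyte genes (-0.20, Gpnmb at -1.22 ± 0.46). The same held for 20 dendritic and Langerhans cell genes (-0.069, Ccl17 at 2.95 ± 0.72, or 0.94 under normexp and above background on 1 of 4 flank arrays, Mgl2 at 1.12 ± 0.32), 44 cell cycle genes (0.20, Ttk at -0.67 ± 0.21, Ccne1 at 0.72 ± 0.40) and 22 immediate early genes (-0.047, Atf3 at -1.77 ± 0.76, Klf4 at 0.62 ± 0.27). At an unadjusted p under 0.05, 1, 1, 0, 1, 1, 1 and 1 of these were lower, in the same order, and 2 dendritic cell genes and 1 immediate early gene were higher. These lists did not pass with all arrays (adjusted p = 0.329, 0.186, 0.413, 0.200, 0.904, 0.449 and 0.322), nor did wound and matrix remodelling (median 0.0096, adjusted p = 0.351), where Mmp9 was the 1 called gene of 20. Fibroblast genes were lower without neck replicate 1 (median -0.36, adjusted p = 0.00686), vessel genes without flank replicate 2 or 4 or neck replicate 1 (medians -0.34, -0.41 and -0.59, adjusted p = 0.0307, 0.0416 and 0.00219), macrophage genes without flank replicate 2, 3 or 4 or number 2 (medians -0.36, -0.40, -0.44 and -0.52, adjusted p = 0.0438, 0.0496, 0.0352 and 0.0120) and immediate early genes without flank replicate 2 or number 2 (medians -0.29 and -0.41, adjusted p = 0.0307 and 0.00384). Vessel genes also passed without flank replicate 1 with the fixed replicate block (0.0350). Cell cycle genes passed with a median of 0.36 without flank replicate 2 and -0.11 without flank replicate 3 (0.0293 and 0.0127), and of -0.046 without number 3 and -0.12 without flank replicates 1 and 3 (0.0448 and 0.0399).

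Of 16 housekeeping genes 0 passed by limma and 5 were higher at an unadjusted p under 0.05, with Ywhaz at 0.98 ± 0.27 and Hprt at 0.87 ± 0.28. The list median was 0.31 (camera adjusted p = 0.0346, adjusted p = 0.701 with an estimated correlation, and exact permutation p = 0.114) and -0.032 after quantile normalization (adjusted p = 0.546). The call also ended with the authors' deposited values (median -0.031, adjusted p = 0.546), under normexp (0.0519) and with the mean of a gene's probes (0.167). It ended with the fixed replicate block (0.0542) and without flank replicate 2 or 3, neck replicate 1 or 3, or number 3 or 4 (0.0960, 0.0690, 0.0587, 0.0834, 0.135 and 0.0546). The median was -0.011, 0.55 and 0.31 on slides 1, 2 and 3 (camera adjusted p = 0.0416 with the slide as a block).

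The median of all genes was 0.10 here, -0.0014 under quantile normalization and -0.033 with the 75th percentile of probes detected on all arrays, which gave 334 higher and 466 lower genes, or 41.8% higher against 56.2%. With the slide as a block 564 genes were higher and 507 lower, and with the random replicate block 996 and 890. Within slide 2, with 2 arrays of each site, 206 genes passed by limma on that slide alone. The counts of higher and lower genes were 656 and 338 without flank replicate 1, 135 and 92 without flank replicate 2, 125 and 96 without flank replicate 3, and 179 and 164 without flank replicate 4. They were 106 and 71 without neck replicate 2, 108 and 79 without neck replicate 3, and 109 and 89 without neck replicate 4. Of the 85 named genes that were called, 34 passed with each of the 8 arrays left out in turn, among them Wfdc12, Fetub, Nmu, Krt1, Tgm3, Hoxa7, Krt77, Il31ra and Cd5, and 61 passed with the fixed replicate block.

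By exact permutation of the array means, p was 0.0286 for the antimicrobial, activated keratinocyte, cornified envelope, ceramide, muscle, white fat and Hox lists, and for the gamma-delta T and cytotoxic lists, which camera did not call or did not test. It was 0.0571 for the cholesterol and Schwann cell lists. Adjusted over all lists the lowest value was 0.117, so no list passed this test. Since 0.0286 is the smallest p that 4 against 4 arrays can give, a pass after adjustment needs many lists at that floor together. The lack of a pass therefore says little about any single list. Under quantile normalization the median was 0.75 for cornified envelope and 0.51 for cholesterol genes, and under normexp it was -0.49 for Schwann cell genes. With each array or number left out, the median ran from 1.58 to 4.73 for hair shaft, -1.28 to -0.38 for melanocyte, 0.56 to 1.87 for neutrophil, -1.09 to -0.49 for Schwann cell and 1.41 to 3.14 for antimicrobial genes. With no filter on dim probes it was 1.20 for antimicrobial, -0.96 for melanocyte and -1.05 for posterior Hox genes. With only probes above background on all arrays it was 2.63 for activated keratinocyte, 0.73 for neutrophil and -1.30 for posterior Hox genes. Some named genes that did not pass on all arrays did so under an alternative. With the random replicate block these were Il17a, Il1rn, Ccl17, Mgl2, Ttk, Zic1, Cpt1b, Sox10 and Ywhaz, and without flank replicate 1 Il17a, Il1rn, Cxcr2, Cxcl5, Ccl17 and Mgl2.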

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

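The tests of explanations in this part were chosen after the result was seen, except the comparison with random lists. In 78 groups of 4 list means and 230 groups of 4 gene values, an array stood far from the other 3 of its site 12 and 13 times, and chance does so in about 1 in 20 groups.

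Flank replicate 1 stood apart most often. Its list means were high for activated keratinocyte genes (4.08), interleukin-1, interleukin-6 and tumor necrosis factor inflammation (2.10), neutrophil and monocyte chemokines (1.68), neutrophils (2.65), macrophages and monocytes (3.27), wound and matrix remodelling (1.62) and itch mediators (0.45), and low for cell junction genes (1.71). Rptn (2.03), Il1f8 (1.92) and Stfa3 (7.04) were high on it too.

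A neck sample under the flank label is excluded by the posterior Hox genes, whose mean was 0.18 on flank replicate 1, 0.24 to 0.74 on the other flank arrays and -3.78 to -2.84 on the neck arrays. Uneven intensity or scaling is excluded by 10000 random lists of like signal, of which 0% stood as far above the other flank arrays (highest 0.50, against 4.31). Neck RNA like that of these 4 samples, mixed into the flank sample, is excluded for macrophage and monocyte genes, since a mixture cannot exceed both sources, and 22 of 25 stood above each of the other 7 arrays (median 1.21, quartiles 0.69 and 1.71, list mean 3.27 against 0.74 to 1.92 on the neck arrays). Activated keratinocyte genes had a list mean of 4.08 against 4.31 to 4.94 on the neck arrays, with 0 of 36 above all other arrays. They needed a median of 67.3% neck RNA (quartiles 36.7% and 91.7%). The 9 called posterior Hox genes needed 14.2% (2.15% and 39.5%), ranges that overlap and do not decide. Of 630 other genes called higher without this array, 117 (18.6%) needed under 9.17%. Hair shaft genes argue against a mixture at the shares that activated keratinocyte genes needed. Their list mean was -1.86 on flank replicate 1 against 2.49 to 4.35 on the neck arrays, and such a mixture would have lifted it towards the neck arrays. A smaller share of neck RNA stays open. A candidate explanation is inflammation of this flank site, which no group of the design tests.

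Neck replicate 1 was low for activated keratinocyte genes (4.31), cholesterol synthesis (3.47) and Il1f5 (5.17), and high for skeletal muscle (3.21). Flank replicate 2 was low for T cells (-1.18), Krt77 (3.33) and Hpgds (-1.93). Flank replicate 3 was high for Actn3 (5.36), Mybpc2 (5.97), Cpt1b (2.73) and Gpx3 (3.48). Fetub was low on flank replicate 4 (-1.26), Serpinb3c high on neck replicate 4 (5.63) and F2rl1 low on neck replicate 2 (-4.02).

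The counts were set against all 35 splits of the 8 arrays into 4 and 4. The real split gave 664 genes and the highest other split 848, while every remaining split gave 0. Thus 2 of 35 splits, the real one included, gave as many, and chance could not be excluded by this count. For differences of at least 2-fold the values were 658 and 778, with 0 in every remaining split. The other split set slide 2 against slides 1 and 3, and with the slide as a block 564 genes were higher and 507 lower in neck skin. Among the 8 splits that part all 4 same-numbered pairs, too few for a share under 0.05, the real one gave 664 genes and the highest other 0, while the other 27 keep both arrays of at least 1 number together. For gene lists 17 splits, the real one included, gave at least the real 16, with 27 in the highest other, so chance could not be excluded.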

How the results depend on the processing

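The alternatives without flank replicate 1 combined with a replicate block, and without flank replicates 1 and 3, were chosen after seeing the data. Apart from tests on fewer arrays or other gene numbers, the cause was not tested. The random replicate block gave 996 higher and 890 lower genes (721 and 760 at least 2-fold). The fixed replicate block gave 297 and 320, called 424 of the 664 again, ended the calls of 24 named genes and of the housekeeping list, added that of Ccl17 (adjusted p = 0.0386) and changed no other call of a named gene or list. The slide as a block gave 564 and 507 (464 lower at least 2-fold), the 75th percentile of probes detected on all arrays 466 lower (459 at least 2-fold) and array weights 589 higher. With no filter on dim probes, which tests 37325 genes, 141 were higher and 98 lower, all at least 2-fold, and 2 earlier calls changed sign. With probes above background on all arrays, 188 were lower (186 at least 2-fold) and 1 changed sign. With an estimated correlation 0 lists were higher and 1 lower. Leaving out an array or number gave 16 to 656 higher and 21 to 338 lower genes (16 to 644 and 21 to 333 at least 2-fold), and 6 to 12 higher and 6 to 11 lower lists. Without flank replicate 1 the fixed replicate block gave 600 higher, all at least 2-fold, and the random one 1468 and 1036 (1083 and 858 at least 2-fold). Without flank replicates 1 and 3, 154 were lower, all at least 2-fold, and the hair shaft list reversed (-0.29). Neither Lyve1 nor Il33 was called. Lyve1 ran from -1.04 without flank replicate 4 to 0.014 without flank replicate 1, and was 0.071 without flank replicates 1 and 3. Il33 ran from -0.12 without replicate 2 to 1.11 without flank replicate 1. Counts stayed within 1.5 times under quantile normalization (291 and 286), the authors' deposited values (294 and 285), normexp (341 and 203), the mean of a gene's probes (389 and 311) and a trended prior (407 and 300), but these settings ended the calls of 16, 17, 10, 2 and 4 named genes, and no filter those of 41. Under the scalings 0 called genes changed sign. Signal over background limits dim genes such as Il4 and Il13.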

Other observations

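Families that share a gene name stem were tested for called genes among all 19768 tested, 474 families in all, with a one-sided hypergeometric test adjusted by Benjamini-Hochberg. This test was chosen after the result was seen, as were the members named, and members are not independent. Of 14 kallikreins 6 were higher in neck skin (adjusted p = 2.72e-05), with Klk12 (4.32 ± 0.59), Klk13 (3.97 ± 0.60) and Klk8 (2.38 ± 0.34) beside Klk14. Of 11 Tmprss serine proteases 5 were higher (adjusted p = 0.000155), among them Tmprss11d (4.41 ± 0.44) and Tmprss11b (2.47 ± 0.31). Genes of protease inhibitor families were higher as well, though which proteases they inhibit was not tested. They were 7 of 19 Serpinb genes (adjusted p = 1.58e-05), including Serpinb12 (4.29 ± 0.50), and 3 of 8 Spink genes (adjusted p = 0.0236), including Spink12 (4.46 ± 0.61). The higher Serpinb genes include Serpinb3a, Serpinb3b, Serpinb3c and Serpinb3d, whose probes were not checked for specificity. Serpinb6e was lower (-3.23 ± 0.62). Late cornified envelope genes (5 of 21, adjusted p = 0.00438), ribonucleases (3 of 7, adjusted p = 0.0174, with Rnase2a at 4.52 ± 0.41) and carboxylesterases (3 of 6, adjusted p = 0.0121, with Ces2g at 2.74 ± 0.35 but Ces1f lower at -2.62 ± 0.37) followed. The family test used the calls of the main fit and was not repeated with a replicate block. The called late cornified envelope genes are members of the cornified envelope list, where the fixed replicate block left 5 higher genes against 18.

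Lower in neck skin were 5 of 11 major urinary protein genes (adjusted p = 4.53e-05), which are near-identical copies whose probes were not checked for specificity. So were 4 of 16 Serpina genes (adjusted p = 0.00690), led by Serpina3j (-3.19 ± 0.44), with Serpina9 higher (3.33 ± 0.55), and 5 of 38 cytochromes P450 (adjusted p = 0.0178), among them Cyp2b9 (-2.07 ± 0.31). The median of the cytochrome family was -0.18 and turned to 0.0022 under normexp, while the medians of the other families named here kept their sign under each scaling. Hoxa (6 of 8, adjusted p = 1.25e-07), Hoxb (6 of 9, adjusted p = 1.85e-07) and Hoxc genes (3 of 6, adjusted p = 0.00690) were the other families with more decreases, and the Hoxa and Hoxb medians were -1.51 and -1.29 under normexp against -3.45 and -2.88.

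The tests on Hox, muscle and fat genes below were chosen after the result was seen, apart from the count of other probes. The fibroblast list had a median of -0.090 (quartiles -0.35 and 0.15), or -0.36 without neck replicate 1, against -3.78 for the 15 called Hox genes. This argues against less fibroblast RNA in the neck samples as the account of the Hox decrease only if fibroblast genes did not otherwise differ between the sites. That was not tested. A fault of single probes stays open for single genes, because called Hox genes had 3 other probes. Of these 2 (66.7%) were lower, those of Hoxb8 and Hoxc6, while that of Hoxb3 was at 0.22. For the Hox genes as a set the calls argue against it. Each gene had its own probe, and 9 posterior and 6 anterior genes were called lower and 0 higher. Axial position of the sampled sites stays open, since over all 24 tested Hox genes Spearman's rho of the difference with the paralog number was -0.22 (permutation p = 0.298 over 100000 resamples), against -0.58 (p = 0.0196) over the 16 Hoxa and Hoxb genes, a subset chosen after the values were seen. Lesion in place of body site cannot be told apart from body site by design. Flank replicate 1, with activated keratinocyte genes near the neck level, had a posterior Hox mean of -0.24 relative to the other flank arrays, but it is 1 array.

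For the decrease of muscle and fat genes, dilution by a larger share of epidermal RNA would by itself lower every deeper cell type alike. Blood vessel genes had a median of -0.22 (quartiles -0.56 and 0.071) against -1.82 for muscle and -1.48 for fat. This argues against dilution as the whole account only if vessel RNA did not otherwise differ between the sites. That condition was not tested, so dilution is not excluded. Without neck replicate 1 the vessel median was -0.59 (lower quartile -0.91) against -2.10 and -1.30, and in pair 4 it was -0.54 against -1.71 for muscle and -0.62 for fat, so that pair alone does not part fat from vessels. Less deep tissue in the neck samples cannot be told apart from a difference of site or lesion, because site, lesion and dissection change together. The muscle and fat medians lay below 0 in each of the 4 pairs, the highest at -0.62, as each of these would give.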
